A study of Linum usitatissimum with 4 samples.

How the data were processed

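The series holds whole-genome bisulfite sequencing of flax (Linum usitatissimum, cultivar JRF-2), a method in which unmethylated cytosines are converted and read as thymine while methylated cytosines stay. Per the labels, seedlings fell into 4 groups: a control, a heat treatment, a treatment with 5-azacytidine (a cytidine analogue that blocks DNA methyltransferases), and 5-azacytidine followed by heat. Each group gave 1 library of shoot apices pooled from 10 seedlings, sequenced as paired reads of 150 bp. Plants grew at 22 ± 2 °C with 16 h of light and 8 h of dark and were 21 days old. Heat was 40 ± 2 °C for 4 h on each of 5 days, and 5-azacytidine was given to seeds as a 1 mM soak for 24 h.

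Trimming, quality control, alignment, methylation calling and testing used Trimmomatic, FastQC, BWA, MethylDackel and methylKit, per the submitters' processing notes, which give no versions in the sources used here. The genome build is also not given in the sources used here. The authors deposited 9 tables, for the 3 treatments against the control in the CG, CHG and CHH contexts (H stands for A, C or T). Per the file headers, each row has a chromosome, a start, an end, a p-value, a q-value, a methylation difference, a distance to a gene start and gene identifiers. The p-values and q-values are the authors' own, from their comparison of a treated library with the control library. The methylation difference is the authors' score in percentage points, as deposited, and its sign was read as treated minus control, which is the methylKit convention and is not stated in the files. If the sign were coded the other way, every "higher" and "lower" in the report would swap.

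Although the tables are presented as differentially methylated regions, each of the 1894 listings spans 1 bp, so the units are single cytosines. A CG or CHG has a cytosine on each strand, and these were not joined. The highest q-value was 0.0499 and the smallest absolute difference 5.01 points, so the lists were taken to hold sites with a q-value below 0.05 and a difference above 5 points. Sites that missed these limits, read coverage and methylation levels per library were not analysed here. The depth behind each site is therefore unknown, and a site missing from a list is not shown to be unchanged. The 1894 listings cover 1648 cytosines on 15 chromosomes, Lu1 to Lu15, with 0 listings on organelle or unplaced sequences. Positions are the deposited starts. Whether these count from 0 or 1 is not stated, so a printed position may be off by 1 bp.

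Gene columns were checked before use. In 8 of the 9 tables, all 194 cytosines that occur in more than 1 table carry 1 gene and 1 distance, and all 209 genes with 2 or more sites imply 1 gene start. In the table of 5-azacytidine plus heat in the CG context, 48 of 101 rows have the same kind of gene identifier as the other tables, and all 48 pairs of gene and distance occur in the heat CG table beside other positions. The other 53 rows use another kind of identifier. Gene columns of that table were not used. Its sites took a gene where another table lists the same cytosine (29 sites) or where they lie between sites of 1 gene (31 sites), and 41 sites have no gene. The strand column was not used, since 91 of the 194 repeated cytosines have different strand entries. Free-text protein hits were not used, since 49 genes have such text in 2 or more tables and 0 of them have 1 text throughout. Family-level descriptions were used, as given for 262 of the 389 genes, with the wording of the earliest occurrence because trailing numbers in some descriptions count up from row to row. The identifiers of 8 genes do not pair 1 to 1, and these genes are named by position. A gene is the authors' nearest gene start, and its distance is negative upstream of that start. Exons, introns and intergenic classes need a gene annotation, which was not used here.

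The results, the naming rule and the gene lists were fixed before the data were examined, apart from the shares by distance to a gene start. Those shares took the place of planned shares per annotation class once the data were seen. The rule names, per comparison and context, the 5 sites with the largest rise and the 5 with the largest fall. It adds sites listed in all 3 comparisons in 1 context (up to the 10 with the largest mean absolute difference) and, per gene list and comparison, the 2 sites with the largest absolute difference. It gave 51, 56 and 66 sites for heat, 5-azacytidine and 5-azacytidine plus heat. The text gives those with a gene description first and summarises the rest. The stretches on Lu9 and Lu14, their bounds and some further list members were chosen after their values were seen. The 11 gene lists were matched by words in the family descriptions: heat shock and chaperones, DNA methylation and chromatin, transposable elements, redox, hormone, transcription factors, cell wall and fibre, protein turnover, signalling, transport, and photosynthesis and plastid. Word matching takes some genes whose function lies outside the name of the list and misses others. Descriptions with the word chloroplastic, for example, are not matched by the plastid list, so a count of 0 concerns the words and not the function. Between 52.9% and 55.7% of the sites of a comparison have a described gene.

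No test across samples was made, since methylation levels per library were not used here and 1 library per group leaves no spread between replicates. The q-values compare 2 libraries, not conditions. Shares are given with exact Clopper-Pearson 95% intervals and medians with binomial order-statistic 95% intervals (the range where values are few), which cover counting error only and treat neighbouring cytosines as independent. Overlaps of 1 bp within a context were found with bedtools 2.31.1 and set beside 1000 random placements of the sites within their chromosomes, up to the largest position listed, since chromosome lengths were not used here. All 3 comparisons share 1 control library, and unchanged groups could not be simulated against it without counts per site. Random placement leaves out that shared control. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9. On simulated lists of 200 and 500 sites, the overlap step recovered 60 of 60 planted shared sites and 54 of 54 with 1 direction, and merging gave 3 of 3 regions. Over the 9 list sizes, with 1000 draws each, the exact interval covered the true share in 94.6% of draws or more and the median interval its median in 94.0% or more, against a nominal 95%. These draws were independent values, with 1 fixed share and a normal distribution. The listed sites are clustered, so this coverage is not shown for them.

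Alternatives fixed at the same time were a q-value below 0.001, a difference of at least 40 points, merging sites of 1 list and direction within 1000 bp, a reciprocal overlap of 50%, identical coordinates, genes named in both lists, each context alone, and an upstream window of 1000 bp in place of 2000 bp. Chosen after seeing the data were the CHH share of the listings under the stricter limits, sharing within 1000 bp, the distance to sites of another context and the restriction to sites listed in 1 comparison. Counts per chromosome length, classes at the midpoint of a region and lists without intergenic sites were also fixed then and were not run.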

Results

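DNA methylation was compared between shoot apices of flax seedlings that were left untreated, heated, treated with 5-azacytidine, or treated with 5-azacytidine and then heated. Each of the 4 groups is 1 library from pooled seedlings, so no value has a replicate error, and the tables give no read coverage, so the depth per library and per site is unknown. Across the authors' 9 deposited tables there were 1894 listings of 1648 single cytosines that differed from the control library: 184 for heat, 566 for 5-azacytidine and 1144 for 5-azacytidine plus heat. Differences are the authors' own values, in percentage points of methylation, treated minus control. A site is called near a gene when that gene has the nearest start in the authors' tables, however far, so no link to the gene is implied. Where a single site is named with its value, a distance over 10000 bp is given. Positions are those of the deposited tables, whose genome build is not given in the sources used here.

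The heat comparison asks where the 5 days of heat left shoot-apex methylation different from the control. Of the 184 listed cytosines 123 were in the CHH context, of which 110 were lower in the heated library and 10.6% (95% interval 5.75 to 17.4) were higher. CG sites were more mixed, with 19 of 48 higher (39.6%, 25.8 to 54.7), and CHG sites had 7 of 13 higher (53.8%, 25.1 to 80.8). In the authors' deposited table for CG, the lowest site was 9872 bp upstream of Lus10016846, described as related to ARR1, a response regulator of cytokinin signalling (Lu12, 6274580, -85.4 points, q = 0.043). The highest CG site in the authors' deposited table was 48673 bp upstream of Lus10006147, described as pyruvate, phosphate dikinase, which forms phosphoenolpyruvate (Lu9, 9364877, 76.3 points, q = 0.043).

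Further CG falls in the authors' deposited table lay near Lus10002925, a PX-domain protein gene (-78.9 points), and Lus10019377, described as the pollen development protein LAP3 (-71.4 points, 29056 bp upstream). The site near Lus10041695, described as a DNA oxidative demethylase or alkylated DNA repair protein, had -55.8 points in the authors' deposited table. A fall of smaller size in the authors' deposited table lay near Lus10003641, described as a clathrin coat assembly protein (-35 points, 16933 bp downstream of its start). Among CHG sites, the authors' deposited table gives -23.5 points 10062 bp upstream of Lus10002410, a soluble NSF attachment protein gene of vesicle fusion, and -15.0 points 13184 bp upstream of Lus10002469, described as a cell division protein kinase. The largest CHH falls in the authors' deposited table, both -92.3 points, lay near Lus10033130, which has no description, and 753 bp downstream of the start of Lus10015736, described as an HNH endonuclease. Near Lus10008263, described as the amino acid carrier lysine histidine transporter-like 5, the authors' deposited table gives -39.2 points in the CHH context. The highest CHH sites in the authors' deposited table, 93.3 and 43.6 points, lay 14939 bp downstream of the start of Lus10008384 and near Lus10008373, which have no description.

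Of the fixed gene lists, transport had 5 sites near 4 genes in the heat comparison, all 5 lower, where 145 of all 184 listings were lower. Among the 5 were sites of Lus10008263 and Lus10001656, the latter described as related to the sugar transporter ERD6-like 4 (-16.7 points in the authors' deposited table). Signalling had 11 sites near 6 genes, with 4 higher and 7 lower. In the authors' deposited table the kinase gene Lus10041426 had 23.9 points at a CG site and the phosphatase gene Lus10008761 had -19.0 points at a CHH site 16616 bp downstream of its start. Transcription factors had 8 sites near 3 genes, with 4 higher and 4 lower, including 11.5 points 18187 bp downstream of the start of Lus10032984 (TCP13) and 11.0 points near the PLATZ-family gene Lus10039989 in the authors' deposited table. Redox had 1 higher site (Lus10010288, described as a subunit of NADH-ubiquinone oxidoreductase, 9.51 points in the authors' deposited table). DNA methylation and chromatin had 1 lower site (Lus10041695, matched by the word demethylase, though its description also reads alkylated DNA repair protein). The words of the other lists matched 0 sites, which does not show that genes with these functions were absent: the ARR1-related gene Lus10016846 is a hormone signalling gene that the words missed. No test across samples was made, since methylation levels per library were not used here and each group is 1 library. Under a q-value below 0.001, 16 CG, 7 CHG and 14 CHH sites were left, and the share of CG sites that were higher was 62.5%. That share went the other way at 20% of 5 sites with differences of at least 40 points and 26.1% of sites in 1 comparison. The direction of CG sites thus depends on the limits. Of CHH sites, 28.6% were higher under that q-value and 33.3% with differences of at least 40 points (6 sites), against 10.6% of all 123.

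The 5-azacytidine comparison asks where the methyltransferase inhibitor, given to seeds, left methylation different in the shoot apex. Falls outnumbered rises in all 3 contexts: 51 of 64 CG sites, 38 of 47 CHG sites and 425 of 455 CHH sites were lower than in the control library. The shares that were higher were 20.3% (11.3 to 32.2), 19.1% (9.15 to 33.3) and 6.59% (4.49 to 9.28). Falls were the more frequent direction over all listings of each comparison, heat without 5-azacytidine included, and every comparison uses the same control library. Part of the excess of falls may therefore come from that library, and an effect of treatment on direction cannot be told apart from it. Within 938 bp on Lu9 (12308213 to 12309151), 6878 to 7816 bp downstream of the start of Lus10011702, described as related to the RING-type E3 ubiquitin ligase ATL42, 20 of 21 listed CG and CHG sites were lower. These 21 sites are 18.9% (12.1 to 27.5) of the 111 CG and CHG sites of the comparison. Their median difference in the authors' deposited tables was -15.2 points. Most of the 21 lie in close pairs, placed as the cytosines on both strands of a CG or CHG would be. They are thus not 21 separate units, although the interval treats them so, and the bounds were chosen after the values were seen.

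The smallest q-value of the comparison in the authors' deposited tables, 2.09e-28, belongs to a CHG site of this stretch at 12308805 (-23.1 points). CHH sites in the same stretch went both ways, with 5 of 9 higher. The lists of the other comparisons hold 0 CG or CHG sites there, and 5-azacytidine plus heat has 4 CHH sites, all lower. That a site is missing from a list says that it missed the authors' limits, and the difference between comparisons was not tested.

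**Figure D1:**
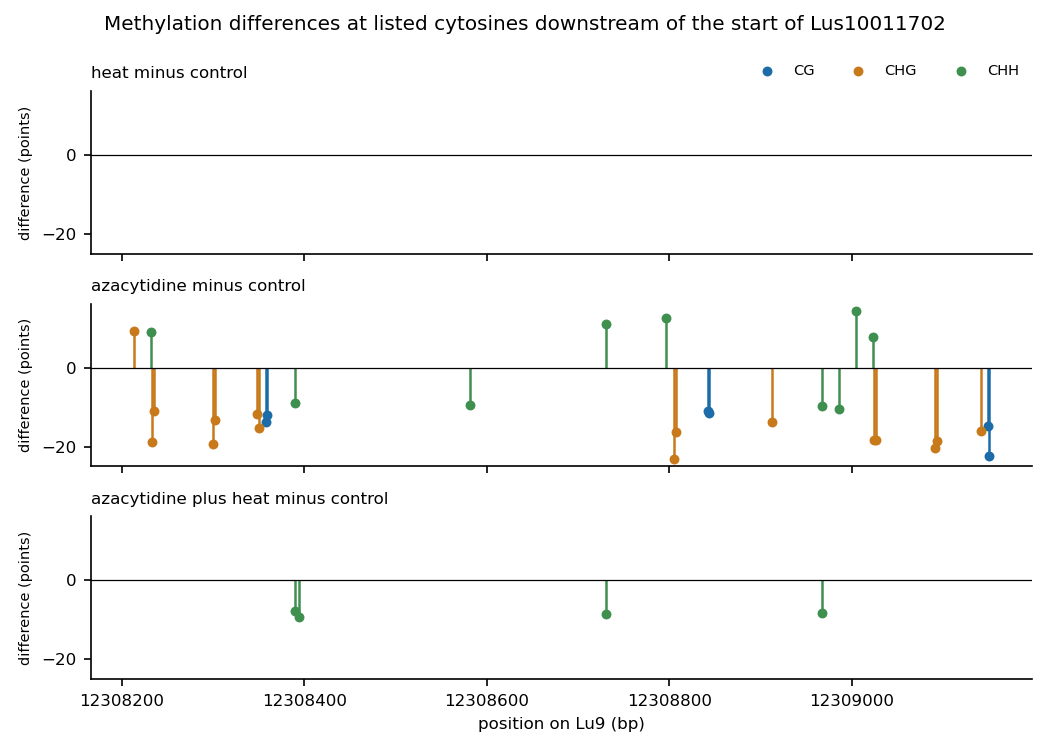
Methylation differences from control in percentage points (vertical axis) at listed cytosines on Lu9 (horizontal axis, position in bp) for heat, 5-azacytidine and 5-azacytidine plus heat, each point being 1 cytosine coloured by context. In the middle panel 20 of 21 CG and CHG cytosines lie below 0, and the top panel has 0 listed cytosines.

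Beyond this stretch, the lowest CG sites in the authors' deposited table lay near Lus10010300, described as a minus-end-directed kinesin, a microtubule motor (-92.3 points, 961 bp downstream of the start), and near Lus10004518, related to ABC transporter B family member 11 (-81.8 points). The site 225 bp upstream of Lus10029201, related to peroxidase 31, had -76.9 points in the authors' deposited table, and the GYF-domain gene Lus10012078 had -71.9 points 10362 bp downstream of its start. The highest CG sites in the authors' deposited table were 91.7 points near Lus10037550, related to the bZIP transcription factor TGA1, and 80.0 points near the DUF393 gene Lus10042142. Rises of 50.9 points near Lus10000739, a DUF4228 gene, and 28.0 points near Lus10034077, described as homoserine dehydrogenase, are also in the authors' deposited table. In the CHG context the authors' deposited table has 91.7 points near Lus10015964, without a description, and -60.2 points 36243 bp downstream of the start of Lus10033213, a glutathione S-transferase-domain gene.

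CHH sites of the 5-azacytidine comparison with the largest falls in the authors' deposited table lay 12823 bp upstream of Lus10002529, related to the potassium channel AKT1 (-92.9 points), and near Lus10043009, related to the cell-cycle regulator CDC20 (-90.9 points). CHH rises in the authors' deposited table included 58.9 points near Lus10004791, a trigger factor chaperone, 57.7 points near Lus10003402, related to potassium transporter 13, and 51.0 points 885 bp upstream of Lus10003777, described as the histone methyltransferase ASHR3. A rise of 47.8 points near Lus10024818, described as isoflavone 2'-hydroxylase, is also in the authors' deposited table.

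Of all 566 listings of the 5-azacytidine comparison 514 were lower, and the counts by list are to be read against that share. By list, protein turnover had 39 sites near 3 genes in this comparison, 33 of them lower, and 34 of the 39 belong to Lus10011702. Signalling had 32 sites near 12 genes, 29 lower, with -69.7 points as far as 287742 bp upstream of Lus10007689, related to an inositol-tetrakisphosphate kinase, in the authors' deposited table. Transport had 12 sites near 8 genes, 11 lower. Redox had 8 sites near 5 genes, all 8 lower, including Lus10029201, Lus10033213 and Lus10014850, described as cytochrome P450 90A1, an enzyme of brassinosteroid synthesis. Transcription factors had 8 sites near 7 genes, 7 lower, with -69.2 points 265 bp downstream of the start of the Myb/SANT-like gene Lus10022379 in the authors' deposited table. Cell wall and fibre had 5 sites near 3 genes, all 5 lower, with -27.7 points near the beta-galactosidase gene Lus10015616 and -22.6 points near Lus10015694, related to arabinogalactan peptide 23, in the authors' deposited table. Heat shock and chaperones had 3 sites, 1 higher and 2 lower, near Lus10004791, Lus10002949 (a tubulin chaperone) and Lus10007031 (a copper chaperone for superoxide dismutase), which are chaperones outside the heat shock families. DNA methylation and chromatin had 1 site, Lus10003777. The words of the remaining lists matched 0 sites, though Lus10014850 is also a hormone gene by function. No test across samples was made. Under a q-value below 0.001 the lists shrank to 20 CG, 17 CHG and 43 CHH sites, with falls still the more frequent direction in each. Most of those 17 CHG sites and part of the 20 CG sites are falls in the Lu9 stretch. The share of CHH sites that were higher rose from 6.59% to 18.6%. With differences of at least 40 points, 33.3%, 33.3% and 23.1% of 9 CG, 6 CHG and 26 CHH sites were higher.

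Treatment with 5-azacytidine before heat asks whether the combined treatment changed methylation elsewhere or further than either alone. Its CG and CHH lists were the longest of the 3 comparisons, while its CHG list was shorter than with 5-azacytidine alone. Of 101 CG, 25 CHG and 1018 CHH sites, 79, 17 and 994 were lower than in the control library. Part of this excess of falls, too, may come from the shared control library. The shares that were higher were 21.8% (14.2 to 31.1), 32.0% (14.9 to 53.5) and 2.36% (1.52 to 3.49). CHH sites made up 89.0% (87.0 to 90.7) of the listings, against 80.4% (76.9 to 83.6) for 5-azacytidine and 66.8% (59.5 to 73.6) for heat. Under a q-value below 0.001 these shares were lower, at 67.9% (58.4 to 76.4), 53.8% (42.2 to 65.0) and 37.8% (22.5 to 55.2), the last no longer a majority. The share of CHH among all cytosines that could be called is not known here, so these shares have no baseline. List lengths and shares also depend on the depth per library, which is unknown. Differences were mostly small, with a median absolute difference of 9.40 points (9.14 to 9.62) at CHH sites and 13.8 points (11.8 to 15.8) at CG sites.

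**Figure D2:**
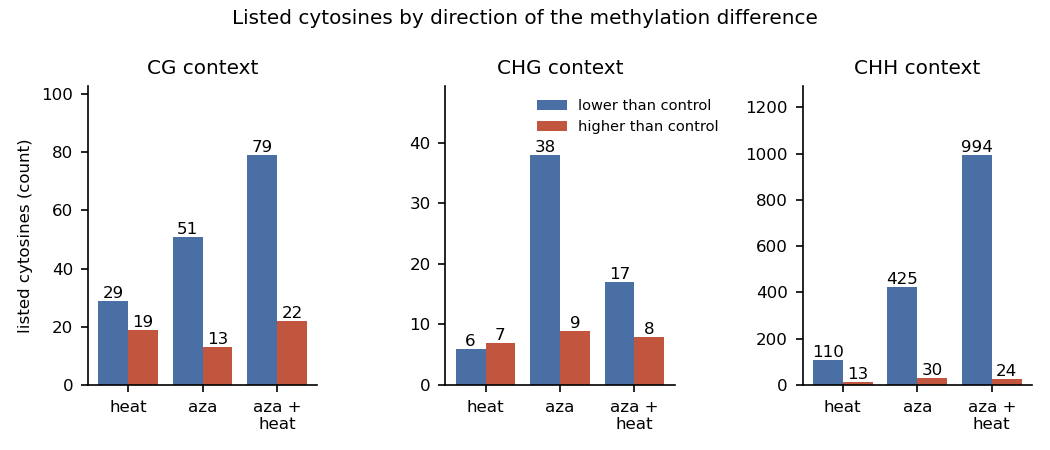
Number of listed cytosines (vertical axis, a separate scale per panel) lower and higher than the control library for heat, 5-azacytidine (aza) and 5-azacytidine plus heat (aza + heat), in the CG, CHG and CHH contexts. The CHH panel rises from 110 lower sites for heat to 425 and 994 for the treatments with 5-azacytidine. Counts also depend on the depth per library, which is unknown.

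Of all 1144 listings of the combined comparison 1090 were lower than control, so a gene list with all its sites lower is near that share. Chaperone genes had sites in this comparison that were all lower, 11 of 11 near 5 genes. In the authors' deposited tables these include -91.7 points at a CHG site 1257 bp downstream of the start of Lus10013882, a 70 kDa heat shock protein gene on Lu6, and -84.0 points at a CHH site 7754 bp upstream of Lus10028103, described as the Hsp90 co-chaperone AHA1. Further members were Lus10028577, an alpha-crystallin-domain heat shock gene, with -14.0 points 566 bp upstream in the authors' deposited table, and Lus10007031 with 7 sites. The 7 sites of Lus10007031, a copper chaperone for superoxide dismutase, are counted again under redox.

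Redox had 15 sites near 4 genes in the combined comparison, all 15 lower, with -52.2 points near the peroxidase gene Lus10000626 in the authors' deposited table. Transport had 24 sites near 8 genes, all 24 lower, with -81.8 points 14198 bp upstream of Lus10007770, related to oligopeptide transporter 6, in the authors' deposited table. Protein turnover had 22 sites near 10 genes, all 22 lower, among them Lus10040075, a protease gene (-78.0 points in the authors' deposited table), and Lus10011640, proteasome subunit beta type 4 (-69.9 points in the authors' deposited table). Cell wall and fibre had 9 sites near 5 genes, all 9 lower, with -84.6 points near the polygalacturonase gene Lus10003782 and -23.0 points near Lus10023775, related to pectinesterase 4, in the authors' deposited table. Signalling had 67 sites near 18 genes, 62 lower, including -75.6 points near Lus10042537, related to the receptor kinase ANXUR1, in the authors' deposited table. Transcription factors had 17 sites near 10 genes, 16 lower, including -93.8 points 11532 bp downstream of the start of Lus10008393 (GTE1) and -73.8 points 1664 bp upstream of the MYB-related gene Lus10008010 in the authors' deposited table.

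The words of the hormone list matched 4 sites near 2 genes in the combined comparison. Of these, 3 were lower near Lus10012675, abscisic acid 8'-hydroxylase, which breaks down abscisic acid, 5122 to 15087 bp downstream of its start (down to -22.8 points in the authors' deposited table), and 1 was higher near the auxin-responsive gene Lus10037443 (18.7 points in the authors' deposited table). Transposable elements had 1 site, -54.6 points 961 bp downstream of the start of the transposase gene Lus10007402 in the authors' deposited table. DNA methylation and chromatin had 2 lower sites, -8.61 points near Lus10001729, related to the histone methyltransferase SU(VAR)3-9, and -8.33 points 13204 bp upstream of Lus10012411, a TAF9 subunit gene, in the authors' deposited table. The words of the photosynthesis and plastid list matched 0 sites, and Lus10039449, a chloroplast ferredoxin-thioredoxin reductase gene with 3 lower sites, was counted under redox.

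Among the largest rises of the combined comparison in the authors' deposited tables were 71.6 points at a CHG site near Lus10042787, alcohol dehydrogenase class P, and 45.7 points at a CHG site near Lus10012938, described as mitogen-activated protein kinase kinase 6. CHH rises in the authors' deposited table included 72.1 points 458 bp upstream of Lus10028354, related to the methyltransferase PMT27, and 70.1 points near Lus10024456, the spindle checkpoint gene MAD1. In the CG context, the sites with the largest differences in the authors' deposited table have no gene here, 92.3 points at 5038747 on Lu13 and -94.1 points at 15503993 on Lu13. The kinase gene Lus10041426 had 46.1 points at 10756361 on Lu15 in the authors' deposited table, the base next to the heat site at 10756362. No test across samples was made. Under a q-value below 0.001, 31 CG, 5 CHG and 76 CHH sites were left, and the share of CG sites that were higher was 41.9%. With differences of at least 40 points, 50% of 12 CG sites and 60% of 5 CHG sites were higher, so the excess of falls does not hold in these contexts under that limit, while 14.6% of 48 CHH sites were higher.

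**Figure D3:**
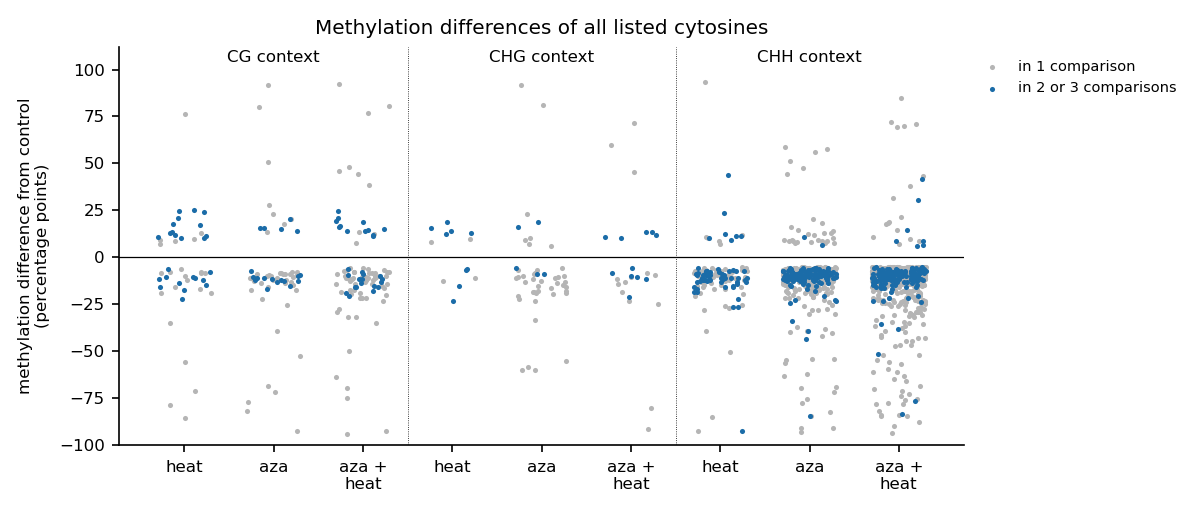
Methylation differences from control in percentage points (vertical axis) of all 1894 listings, by context and comparison (horizontal axis, points spread sideways), with blue points for cytosines listed in 2 or 3 comparisons. Blue points are few beyond 40 points: of the 113 cytosines with differences of 40 points or more 4 are in 2 or 3 lists.

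Sites with differences of 40 points or more, which include most of the extreme sites named above, seldom recurred. Of 113 such cytosines, 4 were in 2 or 3 lists (3.54%, 0.973 to 8.82), against 212 of 1535 cytosines with smaller differences (13.8%, 12.1 to 15.6). A q-value below 0.001 was found for 3 of the 117 listings with such differences (2.56%, 0.532 to 7.31) and for 226 of the 1777 others (12.7%, 11.2 to 14.4).

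The comparisons were then set beside each other to see which cytosines recurred. Heat and 5-azacytidine shared 40 cytosines, heat and 5-azacytidine plus heat 88, and 5-azacytidine and 5-azacytidine plus heat 148, where 1000 random placements gave at most 1. Under a q-value below 0.001 these counts were 8, 27 and 11, so the order of the last 2 pairs was reversed. Most of those 8, and part of the 27 and of the 11, lie in 1 stretch of 89 bp on Lu14, described below. The 88 are 47.8% (40.4 to 55.3) of the heat list, and the 148 are 26.1% (22.57 to 29.98) of the 5-azacytidine list. Direction was the same at all 40, all 88 and 147 of the 148. By gene, 56, 68 and 136 genes were shared by these pairs, and 50 genes had sites in all 3 comparisons. All 3 comparisons use 1 control library, so part of this overlap may come from that library, and random placement does not account for it. The placements also draw from all bases and not only from cytosines that could be called. Their low counts follow from that design, and no conclusion is drawn from them.

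**Figure D4:**
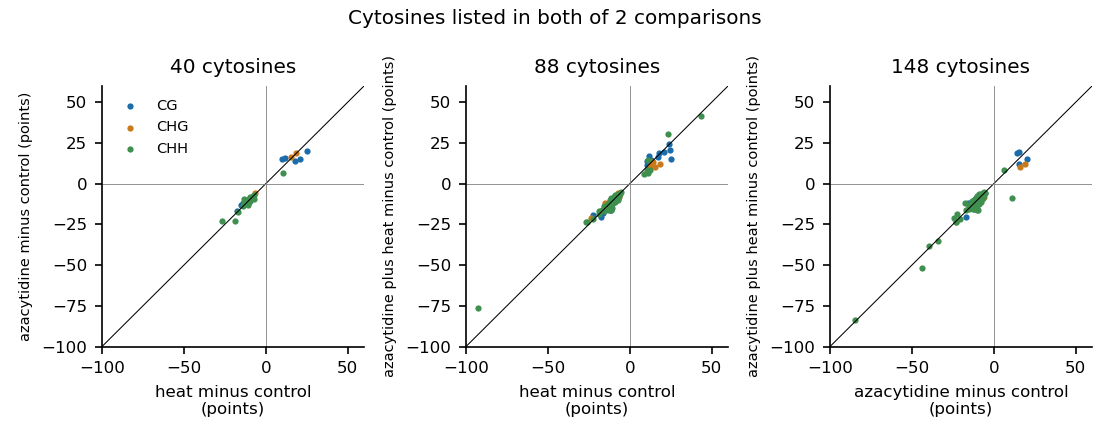
Methylation difference from control in percentage points in 1 comparison (horizontal axis) against another (vertical axis) at cytosines listed in both, coloured by context, with the line of equal differences. The panels hold 40, 88 and 148 cytosines, and 1 point in the right panel has opposite signs.

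In all 3 lists there were 30 cytosines, 7 CG, 3 CHG and 20 CHH, of which 23 were lower in every comparison and 7 higher in every comparison. The largest mean difference belongs to a CHH site at 5825304 on Lu10, with -26.6, -23.2 and -23.8 points for heat, 5-azacytidine and their combination in the authors' deposited tables. Near described genes, CHH sites in all 3 lists were lower at Lus10017173, a suppression of tumorigenicity 5 family gene (-16.8, -17.1 and -16.2 points in the authors' deposited tables), and at Lus10003996, described as the meiotic recombination protein SPO11 (-10.9, -13.2 and -14.9 points in the authors' deposited tables). The same holds at Lus10025047, a pentatricopeptide repeat gene, 1500 bp upstream (-11.1, -10.4 and -15.9 points in the authors' deposited tables). CG sites higher in all 3 lists lay 1817 and 1897 bp upstream of Lus10024541 on Lu13, the latter with 21.1, 15.4 and 19.2 points in the authors' deposited tables, and at Lus10009854 (11.8, 15.6 and 11.8 points in the authors' deposited tables).

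Several recurring sites lay together on Lu14 between the starts of Lus10002716 and of Lus10002717, a serine/threonine protein kinase gene, which the distances place at 8137011 and 8138344 with the stretch upstream of both. Within 89 bp (8137591 to 8137680) there were 17 listed cytosines, 8 of them in all 3 lists, 3 higher and 5 lower in every comparison. Neighbouring bases went opposite ways: the CHG site at 8137629 had 18.7, 18.9 and 12.1 points and the CHH site at 8137630 had -18.5, -22.7 and -18.3 points for heat, 5-azacytidine and their combination in the authors' deposited tables. The CG sites at 8137658 and 8137673 had -17.5, -17.0 and -20.4 points and 25.2, 20.3 and 15.3 points in the authors' deposited tables. No cytosine of the stretch changed direction between comparisons.

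**Figure D5:**
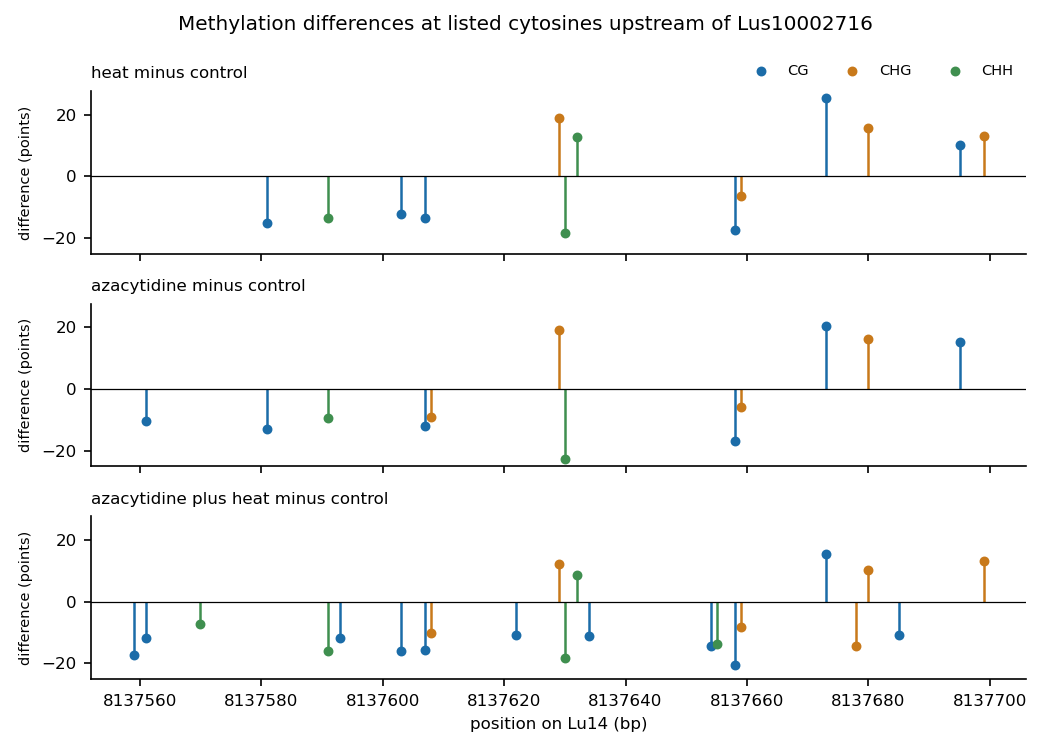
Methylation differences from control in percentage points (vertical axis) at listed cytosines on Lu14 (horizontal axis, position in bp) in the 3 comparisons, coloured by context. The rises at 8137629, 8137673 and 8137680 and the falls at 8137630 and 8137658 stand in the same place in each panel.

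At the 148 cytosines in both lists, 5-azacytidine plus heat differed from 5-azacytidine alone by a median of 0.0547 points (-0.309 to 0.314), a subtraction in which the control cancels. This median is carried by 128 CHH sites (0.0807 points, -0.153 to 0.478). It was -0.745 points at 15 CG sites (-3.38 to 2.21) and -2.27 points at 5 CHG sites, whose values ran from -6.85 to -1.12. Over all sites the difference was below 0 at 71 sites (47.97%, 39.7 to 56.3) and within 5 points at 140 sites. The exception in direction is the CHH site at 12308731 on Lu9 near Lus10011702, with 11.0 points for 5-azacytidine and -8.47 points for the combination in the authors' deposited tables. Sites in both lists are a selected set, since each had to pass the authors' limits against the same control. Whether sites listed in the combination alone were also lower with 5-azacytidine, below those limits, was not analysed here.

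Relative to genes, sites up to 2000 bp upstream of a start made up 19.0% (13.6 to 25.4) for heat, 14.5% (11.7 to 17.7) for 5-azacytidine and 12.4% (10.4 to 14.5) for the combination, the last without its CG table. Median distances were 6704.5, 7014 and 7396 bp, and 39.7%, 36.4% and 40.0% of sites lay over 10000 bp away. In the heat comparison, 13 of the 35 sites in that upstream window were higher, as were 8 of 82 and 9 of 129 in the others. By context, the heat rises were 6 of 13 CG, 5 of 6 CHG and 2 of 16 CHH sites. For 5-azacytidine they were 4 of 12, 2 of 4 and 2 of 66, and for the combination 5 of 10 CHG and 4 of 119 CHH sites. The pooled counts thus depend on the mix of contexts. With a window of 1000 bp the shares were 9.24%, 7.24% and 5.08%. The shares up to 2000 bp depend on the limits: they were 43.2%, 15.0% and 25.9% under a q-value below 0.001, and 9.09%, 17.1% and 15.1% with differences of at least 40 points. Among chromosomes, Lu13 held 31 of the 184 heat sites (16.8%), Lu9 72 of the 566 sites for 5-azacytidine (12.7%) and Lu3 140 of the 1144 sites for the combination (12.2%). Chromosome lengths were not used, so these counts do not show an excess on a chromosome. They are also clustered: Lus10024540 and Lus10024541 each had 11 of the Lu13 sites, Lus10011702 had 34 of the Lu9 sites and Lus10019378 had 24 of the Lu3 sites.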

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

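The count of shared cytosines and of their directions was fixed before the data were examined, and singling out this site was chosen only after the result was seen. At 1 of the 148 cytosines shared by the 5-azacytidine comparison and the combined comparison, the direction differed between the treatments, and this is what drew attention to it. The CHH site at 12308731 on Lu9, 7396 bp downstream of the start of Lus10011702 (related to the E3 ubiquitin ligase ATL42), was higher than the control by 11.0 points with 5-azacytidine (q = 0.000845) and lower, at -8.47 points, with 5-azacytidine plus heat (q = 0.0103), both in the authors' deposited tables. The difference between the treatments was not tested, since each is 1 library and no counts per site were used here.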

How the results depend on the processing

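The stricter limits and merging were fixed before the data were examined, while the CHH share of listings, sharing within 1000 bp, nearness of contexts and the restriction to sites of 1 comparison were chosen after results were seen. No paired analysis was possible because the results come from the authors' differences from control and no levels per library were used here. No group has a replicate to leave out. Reciprocal overlap and identical coordinates gave the same shared sites, since each site is 1 bp. Midpoint classes, lists without intergenic sites and counts per chromosome length were not run, and restricting to assembled chromosomes removes no site. Stricter limits change counts because fewer sites pass, and the depth that sets which sites pass is unknown. For other changes the cause was not tested. Values follow the order CG, CHG, CHH unless named.

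With a q-value below 0.001, heat kept 16, 7 and 14 sites, 5-azacytidine 20, 17 and 43, and the combination 31, 5 and 76. Shares higher moved to 62.5% (heat CG), 28.6% (heat CHH), 18.6% (5-azacytidine CHH), 41.9% (combination CG) and 5.26% (combination CHH). Median absolute differences moved to 12.2 points (heat CHH), 10.5 (5-azacytidine CHH) and 12.2 (combination CHH). Shared sites were 8 (heat and 5-azacytidine), 27 (heat and combination) and 11 (5-azacytidine and combination), the last with 100% in 1 direction. Most of the 8 and part of the 27 and of the 11 lie in the Lu14 stretch. CHH sites made up 37.8%, 53.8% and 67.9% of the listings for heat, 5-azacytidine and the combination. The upstream share became 43.2% for heat, where 10 of the 37 sites are those of the Lu14 stretch, and 25.9% for the combination. Gene lists kept, for heat, 2 transcription factor and 2 signalling sites, for 5-azacytidine, 23 protein turnover, 6 signalling and 1 transport site, and for the combination, 1 redox, 1 transcription factor, 2 cell wall, 2 protein turnover, 9 signalling and 2 transport sites.

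With differences of at least 40 points, heat kept 5 CG and 6 CHH sites and 0 CHG sites, 5-azacytidine 9, 6 and 26, and the combination 12, 5 and 48. Shares higher became 20% and 33.3% for heat (CG and CHH), 33.3%, 33.3% and 23.1% for 5-azacytidine, and 50%, 60% and 14.6% for the combination. Medians became 76.3 and 88.7 points, then 76.9, 60.1 and 60.5, then 72.3, 71.6 and 69.0, as this limit removes all smaller values. Shared sites were 2 for heat and the combination and 2 for 5-azacytidine and the combination (100% in 1 direction), and heat and 5-azacytidine had 0. CHH sites made up 54.5%, 63.4% and 73.8% of the listings. The upstream share was 9.09% for heat and 15.1% for the combination. Lists kept, for 5-azacytidine, 1 chaperone, 4 redox, 2 transcription factor, 2 signalling and 3 transport sites, and for the combination, 2, 1, 3, 5 and 1, with 1 cell wall and 3 protein turnover sites. Lists not named under a limit had 0 sites left or stayed within 1.5 times.

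Merging within 1000 bp gave 30 CHG and 260 CHH regions for 5-azacytidine (10% of the CHH regions higher, median 10.3 points) and 65 CG and 405 CHH regions for the combination (5.68% of the CHH regions higher, median 10.6 points). A window of 1000 bp gave upstream shares of 9.24%, 7.24% and 5.08%. Counting a site of the other list within 1000 bp as shared raised the pairs to 107, 139 and 399. Sites with another context within 1000 bp numbered 71, 171 and 276. The count on the same base was 0, which is fixed in advance because a cytosine has 1 context. Among sites of 1 comparison, 13.9% of the CG sites of the combination and 26.1% of those of heat were higher. In CG or CHG alone, 100% of the sites shared by 5-azacytidine and the combination had 1 direction.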

Other observations

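The counts per gene and the tests of the shared control, heat alone, a common response, thin coverage, a response of 1 treatment and carried-over columns were chosen only after the result was seen. The number of shared sites and their direction were fixed beforehand. Listings were concentrated near few genes, picked here after counting. The 20 genes with the most listings, of 381 whose identifiers pair 1 to 1, hold 646 of the 1894 listings (34.1%, 32.0 to 36.3). Of the 646, 588 are lower than control. Over all listings, 145 of 184 were lower for heat, 514 of 566 for 5-azacytidine and 1090 of 1144 for the combination. Part of this excess of falls may come from the control library that the comparisons share, which was not tested. Lus10024540 on Lu13 leads with 73 listings at 64 cytosines, 10542 to 30868 bp upstream of its start, followed by Lus10006013 on Lu5 with 55 listings, 54 of them lower, 14783 to 26747 bp downstream of its start. Both lack a description. Described genes with the most listings were Lus10011702 on Lu9, related to ATL42, with 45 (39 lower, 6 higher, 6878 to 12170 bp downstream of its start), and Lus10009768 on Lu13, a DUF4370 gene, with 39 (36 lower, 10791 to 35634 bp upstream). Further down, Lus10002410, the soluble NSF attachment protein gene on Lu2, had 30 listings (28 lower, 6691 to 11700 bp upstream), and Lus10019377, the LAP3 gene on Lu3, had 27 (26 lower, 19086 to 41706 bp upstream).

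Some described genes, picked after counting, had falls at every listing. Over all CHH listings, 110 of 123 were lower for heat, 425 of 455 for 5-azacytidine and 994 of 1018 for the combination. Falls at every listing therefore do not set such genes apart. Lus10010175 on Lu9, described as related to SDE3, an RNA helicase of RNA silencing, had 13 listings at 11 cytosines, 3240 to 4287 bp upstream, all 13 lower, with a median of -10.2 points in the authors' deposited tables. Lus10008540 on Lu8, a serine/threonine protein kinase gene, had 22 listings, all lower and all CHH, 6 with 5-azacytidine and 16 in the combination. Lus10017173 on Lu3 had 25 and Lus10013917, described as a sterol regulatory element-binding protein, had 15, all lower. Lus10007390, described as related to bifunctional nuclease 1, went both ways, with 8 higher and 14 lower within 830 bp.

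The recurrence of sites with 1 direction has technical and biological candidates. Heat exposure alone could not put 40 sites of the heat list in the unheated 5-azacytidine list too. That follows from the design whatever the count, so it does not bear on heat as a cause at the other sites of the heat list. A chance value in the shared control would move every comparison alike, and 99.3% of shared sites or more had 1 direction in each pair. That share does not decide, since each shared site had to pass the limits against the same control in both lists, which makes directions alike under other explanations too. A response common to all treatments, such as one to handling or stress, would look the same, and with 1 control library it cannot be told apart from the shared control.

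Large differences rarely recurred, which may reflect thin read coverage. At equal depth a difference of 40 points or more would give smaller q-values than a small one, yet 2.56% of such listings had a q-value below 0.001, against 12.7% of the others. The values are consistent with few reads behind many of the largest differences, which include sites named in the report. A response of 1 treatment only stays open, since each treatment has 1 library and recurrence within a treatment was not measured.

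The gene columns of the CG table of 5-azacytidine plus heat are consistent with columns carried over from the heat CG table: 48 of 48 entries with that kind of identifier hold a gene and distance pair of the heat CG table. Genes read directly from those columns would likely be wrong for these entries. No biological explanation was tested for this pattern.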
